A study of Homo sapiens with 42 samples.

How the data were processed

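Per the submitters' processing notes, reads of the bulk RNA libraries were trimmed with cutadapt and aligned with STAR and Bowtie2, and SAMtools was used, with no versions given. For tRNA and genomic DNA the notes name bedtools 2.27.0, cutadapt 2.6, STAR, SAMtools and Picard. The genome build was hg38. The steps by which sites were called are not given in the sources used here. The fraction values of the bulk RNA tables are the share of changed reads per site and replicate as deposited, and no count stands beside them. Each count in the tRNA and genomic DNA tables is a number of reads over an adenosine, or of those with the change, as deposited by the authors. The p-value columns hold the authors' adjusted p-value against control, with an unadjusted p-value beside it for genomic DNA, and every listed bulk site had an adjusted one under 0.05 in both replicates. In the deposited files, 12 columns of values were not used. The protocol names SMART-Seq v4 for the single cells and the sample titles name Smart-seq2.

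Rates were compared over sites called for both constructs: 443249 sites for NES against NLS, 356643 for ERM against NES and 276293 for ERM against NLS in HEK293T poly(A) RNA, 423471 in K562 and 201162 in rRNA-depleted RNA. The rate of a gene in a library was the mean over its shared sites, and genes with at least 5 of them were tested. The log2 rates were compared with limma 3.58.1 in R 4.3.3, with a trend of the variance on the log2 number of sites, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The plan written before the data were examined named a count model for counts per library and percentiles without a p-value for pooled counts. The files held fractions per library without counts, so limma on gene means was chosen after the files were read, and the planned percentiles of lists are given as well. In the plan nothing was centred. Because the median gene moved by more than 0.1 log2 in poly(A) comparisons, changes are given relative to that median, with both splits of the calls. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between libraries. In rRNA-depleted RNA almost all genes had the same standard error, pooled over genes, which makes p-values of large changes very small.

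Gene lists were fixed before the data were examined: ER-targeted mRNAs (74 symbols), cytosolic mRNAs (50 symbols and the ribosomal proteins), nuclear-retained RNAs (15 symbols and small nuclear, Cajal body and nucleolar RNAs), cytoplasmic long noncoding RNAs (12), nuclear-encoded mitochondrial mRNAs (29), erythroid mRNAs (19), mRNAs with sites of the endogenous ADAR enzymes (24), histone mRNAs and mitochondrially encoded RNAs. TFRC stands in the ER-targeted and the erythroid list. Lists of G2/M mRNAs (60 symbols) and S phase mRNAs (45) were compiled after the data had been examined, and the G2/M list shares TUBB4B with the cytosolic list. Each list's median change was placed among 10000 random lists of the same size, drawn from 5 by 5 bins of mean rate and of a depth proxy, the authors' adjusted p-value set against the rate. A list stood apart when it lay outside the middle 95% of these lists. Members higher and lower were counted with adjustment over all genes and over the list alone. Of 11671 single gene symbols, 98.7% were found in the RefSeq table. XIST and Y-linked genes were left out of the gene-level analysis.

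Genes named are list members, at most 6 per list and comparison by most shared sites, and the 6 largest changes in each direction past the threshold and alike in every replicate. Some genes that this rule selects are not reported here. The 6 sites of highest rate with at least 100 reads were named in tRNA and genomic DNA. The number of shared sites stood in for coverage in this rule, because the depth of the fraction tables is unknown. Mean rates of libraries were compared by exact two-sided permutation, and positions in total RNA by exact sign permutation across positions. tRNA positions and genomic sites with at least 20 reads in both libraries were compared by Fisher's exact test, two-sided and Benjamini-Hochberg adjusted, in scipy 1.17.1. Intervals are exact binomial and cover counting error only. Unpaired probabilities came from ViennaRNA 2.7.2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

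The tests were tried on simulated or altered data. For limma, values were drawn around each gene's mean with its replicate spread, independently for each gene and library. In each run 200 genes were moved, in equal parts by 0.5 and 1 log2. Of those moved by 1 log2, limma recovered 78% (1 false call in the run) for NES against NLS in HEK293T poly(A) RNA, 85% (6) for ERM against NES, 81% (4) for ERM against NLS, 78% (3) in K562 and 0% (0) in rRNA-depleted RNA. A shift shared by all genes of a library was not simulated, so false calls from such shifts were not counted. The rRNA-depleted NES replicates differed by a median of -0.34 log2. For a move of 0.5 log2 the shares were 41%, 46%, 48%, 55% and 0%. With each rRNA-depleted library centred on its median gene, 22% and 65% of genes moved by 0.5 and 1 log2 were recovered. Of 200 random lists of 30 genes, 4.5%, 3%, 2.5%, 5.5% and 3.5% lay outside the middle 95% in the 5 comparisons, and of lists moved by 0.3 log2, 81%, 100%, 84%, 71% and 99% were found. Fisher's test recovered 60.5% of 200 tRNA positions raised by 10 points, with 0 false calls.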

Results

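The series measured A-to-G changes written into RNA by TadA-8e, an adenosine deaminase whose product, inosine, is read as G. The enzyme carried a nuclear export signal (NES, cytoplasm), a nuclear localisation signal (NLS, nucleus) or an endoplasmic reticulum membrane signal (ERM), and control cells received a GFP plasmid. Cells were HEK293T, a line from human embryonic kidney, and K562, a human erythroleukaemia line. The 42 libraries fell into 20 groups, 10 of the libraries were controls and 10 were single cells. Poly(A), rRNA-depleted and total RNA groups held 2 libraries each, and tRNA and genomic DNA groups held 1 each. The RNA tables of the bulk libraries list called sites with a fraction of changed reads per replicate, so the depth behind each fraction is unknown, and control rates at these sites were not analysed here.

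In poly(A) RNA more sites were called with NES than with NLS or ERM, and at higher mean rates. The amount of each enzyme was not analysed here and the depth of each library is unknown. These differences therefore cannot be assigned to the place of the enzyme alone. HEK293T poly(A) RNA carried 907935 sites with NES, 574863 with NLS and 371699 with ERM. The mean rate over these sites was 11.1% ± 0.0226 (SD, n = 2) with NES, 8.80% ± 0.213 with NLS and 8.99% ± 0.132 with ERM. Over the 272035 sites called for all 3 constructs, the means were 14.6%, 8.59% and 8.72%. K562 poly(A) RNA carried 945447 sites at 13.6% ± 0.0413 with NES and 560441 sites at 10.2% ± 0.0983 with NLS. In rRNA-depleted HEK293T RNA there were 345061 sites at 19.5% ± 2.66 with NES and 340436 sites at 18.95% ± 0.0873 with NLS. The NES replicates there stood at 17.6% and 21.4%, and their difference from the NLS mean changed sign with the replicate left out: it was 2.43 points without NES replicate 1 and -1.33 points without NES replicate 2. An exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.333. The difference between NES and NLS or ERM in poly(A) RNA reached that limit, with both NES libraries above both others, while NLS against ERM gave an exact p of 0.667 and NES against NLS in rRNA-depleted RNA an exact p of 1.

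**Figure D1:**
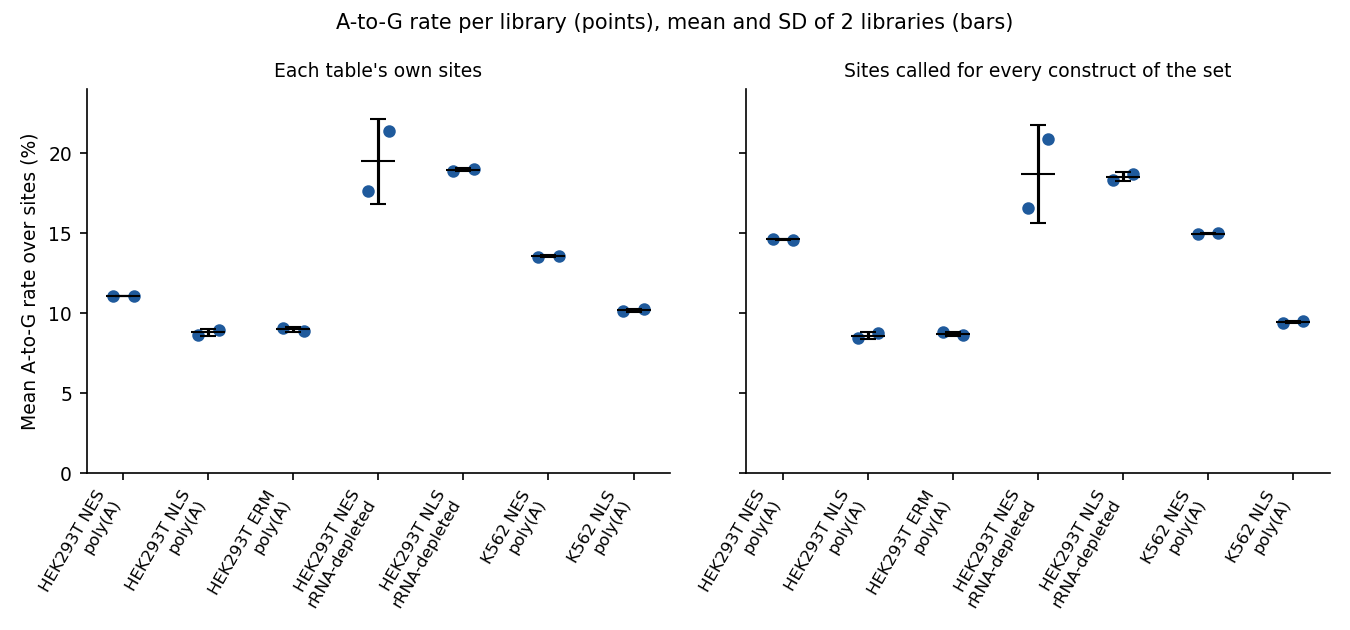
Mean A-to-G rate in percent (vertical axis) of each library, by cell line, RNA and construct. The left panel covers the sites of each library's own table, and the right panel the sites called for every construct of the set. Points are libraries, and lines are means with SD bars. In the left panel the HEK293T NES poly(A) libraries sit at 11.1%, above those of NLS (8.65% and 8.95%) and ERM (9.09% and 8.90%).

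The first gene-level comparison asked which transcripts were reached more from the cytoplasm and which more from the nucleus in HEK293T poly(A) RNA. MAT2A on chromosome 2, which encodes an enzyme that makes S-adenosylmethionine, stood lowest with NES, at 2.15% ± 0.180 against 14.8% ± 0.745 with NLS over 39 shared sites. Also lower with NES were CLK1, a kinase of SR splicing factors, which had 5.12% ± 0.00580 against 15.3% ± 0.925, and RBM5, an RNA-binding regulator of splicing, with 6.41% ± 0.0131 against 19.4% ± 2.06. Higher with NES were FKBP5, a co-chaperone of steroid receptors (24.4% ± 0.176 against 6.17% ± 0.586), and MRPS12, a protein of the mitochondrial ribosome (18.8% ± 0.799 against 4.60% ± 0.666). The median of the 6738 tested genes was higher with NES by 0.66 on the log2 scale, and changes are given relative to that median. As deposited, 5243 genes were higher with NES and 411 lower at an adjusted p under 0.05 in limma, so 92.7% of the calls were higher. Relative to the median gene, 2218 were higher and 2150 lower, or 50.8% higher. On this relative scale MAT2A was lower by log2 -3.44 ± 0.09 (SE, adjusted p = 1.5e-12), TSPYL2 stood at -2.49 ± 0.10, PNISR at -2.27 ± 0.07, RBM5 at -2.25 ± 0.09 and CLK1 at -2.24 ± 0.06. SCAND1 was higher by 1.90 ± 0.18 (adjusted p = 3.4e-07), TOE1, a nuclear deadenylase, by 1.47 ± 0.19, MRPS12 by 1.38 ± 0.15, MGST2, a microsomal glutathione transferase, by 1.37 ± 0.14, NTMT1, an N-terminal methyltransferase, by 1.36 ± 0.14 and FKBP5 by 1.33 ± 0.09. SCAND1 and TOE1 rested on 5 shared sites each. The gene named FRMD8 in the table stood at -3.25 ± 0.12, but 229 of its NLS sites lay inside the interval of the neighbouring nuclear RNA NEAT1 and 0 inside that of FRMD8, so its value cannot be assigned to FRMD8 mRNA.

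Among the lists fixed by place, mRNAs translated on free ribosomes (ribosomal proteins, translation factors, glycolytic enzymes, cytoskeleton) were higher with NES in HEK293T poly(A) RNA. Of 129 measured members, 109 were higher relative to the median gene and 7 lower (109 and 7 adjusted over the list alone), and the list's median lay 0.20 log2 above that of matched random lists, at percentile 99.99. HSPA8, a cytosolic chaperone, was higher by 0.88 ± 0.04 and HSP90AA1 by 0.27 ± 0.03. EEF1A1, a translation elongation factor, stood at -0.32 ± 0.04 relative to the median gene but at 0.34 as deposited, and at 0.33 relative to the median gene when the median of its site rates was used. Nuclear-encoded mitochondrial mRNAs were higher for 24 of 28 members and lower for 1 (24 and 1 adjusted over the list alone, and 28 and 0 as deposited), at percentile 98.5. The list did not stand apart without NES replicate 1 (percentile 93.6), with the median of site rates (86.3), the mean of log2 site rates (90.8) or sites of all 3 constructs (95.3). CYCS, cytochrome c, was higher by 0.56 ± 0.05 and the chaperonin HSPD1 by 0.41 ± 0.04. ER-targeted mRNAs (those of ER, secreted or membrane proteins) were higher for 40 of 69 members and lower for 16 (41 and 16 adjusted over the list alone), and their median equalled that of matched lists (percentile 50.3). CANX, calnexin of the ER membrane, was higher by 0.52 ± 0.04, whereas CALU, calumenin, stood at -0.20 ± 0.05 relative to the median gene and at 0.46 as deposited, and did not pass without NES replicate 1 (adjusted p = 0.086) or without a trend in limma (0.057). Without that library the ER-targeted median lay at -0.06 from matched lists. As deposited, 127 cytosolic mRNAs were higher and 1 lower, and 61 ER-targeted mRNAs higher and 1 lower. The cytosolic list stood apart only where the median gene moved by 0.66, -0.66 or 0.72 log2, and in the direction of that move. At median moves of 0.13 (ERM against NLS) and 0.03 (rRNA-depleted RNA) it lay at percentiles 83.3 and 88.1. Whether this list merely follows a shift of all genes more strongly was not tested, so its place does not by itself show an effect of place in the cell.

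Nuclear-retained RNAs had 5 measured members here, of which 0 were higher and 2 lower relative to the median gene (0 and 2 adjusted over the list alone) but 3 higher and 1 lower as deposited, at percentile 25.6. TUG1, a long noncoding RNA, carried 5.03% ± 0.146 with NES and 14.6% ± 0.580 with NLS (-2.19 ± 0.06). MALAT1, a long noncoding RNA of nuclear speckles on chromosome 11, had 0 called NES sites and 274 NLS sites at a mean of 20.3%, between positions 65499143 and 65505750 of hg38. The percentile of 25.6 leaves it out, since it covers only members with at least 5 shared sites. By number of called sites, which also moves with abundance and depth, 8 nuclear-retained members lay -2.29 log2 from matched lists (percentile 0). Cytosolic mRNAs lay low by that number too (-0.50, percentile 0). Cytoplasmic long noncoding RNAs were higher for 5 of 10 members and lower for 2 (6 and 2 adjusted over the list alone, 9 and 1 as deposited, percentile 75.9): ZFAS1 was higher by 0.52 ± 0.07, and the snoRNA host SNHG1 lower at -1.47 ± 0.06. Of the mRNAs known to carry sites of the cell's own ADAR enzymes, 5 of 16 were higher and 5 lower (5 and 5 adjusted over the list alone, 12 and 1 as deposited, percentile 40.3), with the cyclin CCNI at 0.92 ± 0.06 and MDM2, the p53 ubiquitin ligase, at -1.16 ± 0.04. Erythroid mRNAs had 5 members, 3 higher and 0 lower (3 and 0 adjusted over the list alone, and 5 and 0 as deposited), at percentile 95.2 (98.1 without NLS replicate 2), among them UROS of haem synthesis at 0.84 ± 0.14. Histone mRNAs had 3 members, 0 higher and 1 lower (0 and 1 adjusted over the list alone, 2 and 1 as deposited, percentile 47.3), with H2BC5 at -1.25 ± 0.18. Their median moved from -0.01 to 0.21 against matched lists without NES replicate 1 and to 0.20 without NES replicate 2.

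The ERM construct was set against NES to ask which transcripts were reached more at the ER membrane. Nearly all genes carried lower rates with ERM: of 6883 genes, 6279 were lower and 4 higher as deposited, with a median of -0.66 on the log2 scale. ACTG1 on chromosome 17, a cytoplasmic actin, had 2.20% ± 0.0208 with ERM and 10.5% ± 0.116 with NES over 101 shared sites, and ACTB, the other cytoplasmic actin, had 1.92% ± 0.0473 against 6.80% ± 0.102. Relative to the median gene, ACTG1 was lower at -1.59 ± 0.05 (adjusted p = 1.1e-08), the neurofilament gene NEFM at -1.44 ± 0.12, ACTB at -1.16 ± 0.04, INSIG1, an ER protein of sterol control, at -1.15 ± 0.13 and TMSB10, an actin-binding thymosin, at -1.09 ± 0.13. LONRF1, with 22.7% ± 2.24 against 15.5% ± 0.797, was higher by 1.21 ± 0.17 (adjusted p = 0.00054), PAGR1 by 1.21 ± 0.16, MTARC1 of the outer mitochondrial membrane by 1.07 ± 0.14 and the homeobox gene BARX2 by 1.01 ± 0.15. These 4 were also the genes called higher as deposited, while the amino acid transporter SLC7A6 (0.97 ± 0.20) and the galactose mutarotase GALM (0.95 ± 0.17) passed only relative to the median gene, with 0.31 and 0.29 as deposited, and SLC7A6 did not pass without ERM replicate 1 (adjusted p = 0.067). With the median of site rates neither SLC7A6 (0.71, adjusted p = 0.053) nor GALM (0.64, adjusted p = 0.060) passed. The count of 4 was 1 without ERM replicate 1 and 8 without NES replicate 2. Relative to the median gene, 886 genes were higher and 1442 lower with ERM, so that 38.1% of calls were higher against 0.0637% as deposited.

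Cytosolic mRNAs fell below the median gene with ERM: 106 of 129 were lower and 1 higher (112 and 2 adjusted over the list alone), against 129 and 0 as deposited, and the list's median lay -0.11 log2 from that of matched lists, at percentile 0. HSP90AA1 stood at -0.63 ± 0.02 and EEF1A1 at -0.72 ± 0.03. The number of called sites went the other way: for ERM against NES the list lay 0.58 log2 above matched lists (percentile 100), and for NES against NLS it lay at -0.50 (percentile 0). This was not particular to cytosolic mRNAs, since for ERM against NES site numbers also lay above matched lists for ER-targeted mRNAs (0.22, percentile 100), nuclear-encoded mitochondrial mRNAs (percentile 99.99), cytoplasmic long noncoding RNAs (99.8), erythroid mRNAs (99.7) and mitochondrially encoded RNAs (2.24, percentile 100). ER-targeted mRNAs were lower for 30 of 70 members and higher for 14 (36 and 16 adjusted over the list alone), against 68 and 0 as deposited, and their median lay at percentile 9.78. CANX stood at 0.07 ± 0.02 relative to the median gene (adjusted p = 0.036), but at -0.60 as deposited and at -0.08 when the median of site rates was used. It did not pass without NES replicate 1 (adjusted p = 0.27) or NES replicate 2 (0.16), without a filter on sites (0.41) or without a trend in limma (0.43). HSP90B1, the ER chaperone, stood at -0.25 ± 0.03. Nuclear-encoded mitochondrial mRNAs were lower for 14 of 28 and higher for 0 (16 and 1 adjusted over the list alone, and 28 and 0 as deposited), at percentile 63.2, with HSPD1 at -0.57 ± 0.02. The list's median moved from 0.02 above matched lists to -0.06 without ERM replicate 1 and -0.0043 without NES replicate 1. Of 4 nuclear-retained RNAs, 1 was higher and 0 lower relative to the median gene (1 and 0 adjusted over the list alone) but 0 higher and 4 lower as deposited, at percentile 91.9, or 98.6 without ERM replicate 1. That gene was JPX, at 0.35 ± 0.10 relative to the median gene and -0.32 as deposited, and it did not pass without ERM replicate 2 (adjusted p = 0.15), NES replicate 1 (0.062) or NES replicate 2 (0.058), with the median of site rates (0.13) or over sites of all 3 constructs (0.058). Of 10 cytoplasmic long noncoding RNAs, 1 was higher and 3 lower (1 and 4 adjusted over the list alone, and 0 and 10 as deposited), at percentile 45.5 and at 76.8 without ERM replicate 1, with DANCR at 0.43 ± 0.10 (-0.23 as deposited; adjusted p = 0.074 without ERM replicate 1 and 0.060 without a trend in limma) and SNHG1 at -0.87 ± 0.07. Of the ADAR-site mRNAs 5 of 16 were lower and 0 higher (5 and 0 adjusted over the list alone, 14 and 0 as deposited, percentile 19.2), among them COPA, a COPI coat protein, at -0.49 ± 0.03. Of 5 erythroid mRNAs, 1 was higher and 1 lower (1 and 1 adjusted over the list alone, 0 and 5 as deposited, percentile 87.3, or 99.4 over sites of all 3 constructs). The histone list had 1 measured member and was not compared.

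ERM was set against NLS for the same question with the nucleus as the reference. Among the genes lower with ERM, MAT2A had 3.62% ± 0.258 against 22.9% ± 0.328, OGT, which attaches O-linked N-acetylglucosamine, 4.05% ± 0.128 against 20.1% ± 0.255, EIF4A2, a translation initiation helicase, 3.12% ± 0.000612 against 15.1% ± 0.302, and the splicing factor SRSF5 2.40% ± 0.201 against 11.6% ± 0.0974. FKBP5 was higher, at 18.8% ± 0.181 against 6.42% ± 0.655, as was CHMP3, an ESCRT protein, at 24.2% ± 1.13 against 8.19% ± 0.272. The median of the 5825 genes was higher with ERM by 0.13. Calls were 2360 higher and 1308 lower as deposited (64.3% higher) and 1738 and 1813 relative to the median (48.9% higher). On the relative scale MAT2A stood at -2.80 ± 0.10 (adjusted p = 4.8e-10), OGT at -2.44 ± 0.08, LENG8, SRSF5 and EIF4A2 at -2.41 each (SE 0.13, 0.09 and 0.06) and SNHG1 at -2.33 ± 0.07. CHMP3 was higher by 1.43 ± 0.13 (adjusted p = 1.2e-06), FKBP5 by 1.42 ± 0.09, RCAN1, an inhibitor of calcineurin, by 1.36 ± 0.15, MGST2 by 1.35 ± 0.13, MRPS12 by 1.35 ± 0.16 and SRRD by 1.33 ± 0.17.

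For ERM against NLS, ER-targeted mRNAs were higher for 21 of 66 members and lower for 19 (21 and 19 adjusted over the list alone, 33 and 12 as deposited, percentile 53.5), with CANX at 0.46 ± 0.05. The median of that list moved from 0.01 above matched lists to -0.04 without ERM replicate 1 and -0.05 without ERM replicate 2. Cytosolic mRNAs were higher for 55 of 128 and lower for 38 (57 and 38 adjusted over the list alone, and 76 and 27 as deposited), at percentile 83.3 and at 97.54 without NLS replicate 1, with HSP90AA1 at -0.50 ± 0.04 and EEF1A1 at -1.08 ± 0.04. Cytoplasmic long noncoding RNAs were higher for 6 of 10 and lower for 3 (6 and 3 adjusted over the list alone, and 7 and 3 as deposited), at percentile 98.1, which became 92.4 without NLS replicate 1, 93.0 without NLS replicate 2, 95.6 among lists matched on rate alone and 92.0 with no filter on sites, so that the list no longer stood apart. DANCR was higher by 0.76 ± 0.09 and ZFAS1 by 0.44 ± 0.07. Nuclear-encoded mitochondrial mRNAs were higher for 15 of 28 and lower for 5 (16 and 5 adjusted over the list alone, 20 and 3 as deposited, percentile 88.1), with CYCS at 0.43 ± 0.05. Of 3 nuclear-retained RNAs 0 were higher and 2 lower (0 and 2 adjusted over the list alone, 1 and 1 as deposited, percentile 22.9), and with no filter on sites the list's median moved from -0.25 to -1.66 against matched lists (percentile 0.015). TUG1 had 5.86% ± 1.10 against 22.4% ± 0.599 (-2.08 ± 0.12). ADAR-site mRNAs were higher for 4 of 15 and lower for 6 (4 and 6 adjusted over the list alone, 5 and 4 as deposited, percentile 8.39), with MDM2 at -1.34 ± 0.04. Erythroid mRNAs were higher for 2 of 4 and lower for 0 (2 and 0 adjusted over the list alone, 3 and 0 as deposited, percentile 80.7), with UROS at 0.98 ± 0.12.

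K562 cells were used to ask the NES against NLS question in a second line. MALAT1 stood lowest with NES, at 3.27% ± 0.0791 against 36.4% ± 1.5 over 32 shared sites on chromosome 11. TXNIP, the thioredoxin-interacting protein, had 3.80% ± 0.133 against 13.5% ± 0.0673, and ARRDC3, of the same arrestin family, 7.97% ± 0.112 against 32.4% ± 0.691. Higher with NES were 3 genes of ribosomal proteins: RPL23 had 8.14% ± 0.244 against 1.39% ± 0.0473, RPS27A 9.58% ± 0.151 against 1.85% ± 0.0704 and RPS20 9.17% ± 0.0768 against 1.84% ± 0.115. The median of the 6523 genes was higher with NES by 0.72. As deposited 5229 genes were higher and 384 lower (93.2% higher), and relative to the median 2437 and 2432 (50.1% higher). On the relative scale MALAT1 stood at -4.20 ± 0.07 (adjusted p = 2.2e-09), GOLGA8A at -2.99 ± 0.09, ARRDC3 at -2.74 ± 0.09, LENG8 at -2.60 ± 0.13, TXNIP at -2.55 ± 0.03 and FRMD8 at -2.44 ± 0.07, the last with 435 of its NLS sites inside the NEAT1 interval and 4 inside its own. RPL23 was higher by 1.83 ± 0.05 (adjusted p = 1.7e-08), GTF2H5, a TFIIH subunit, by 1.66 ± 0.15, TOMM6, of the mitochondrial import pore, by 1.65 ± 0.07, RPS27A by 1.65 ± 0.04, RPS20 by 1.60 ± 0.05 and CKS1B, a cyclin-dependent kinase subunit, by 1.60 ± 0.07.

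Cytosolic mRNAs were higher with NES in K562 for 120 of 129 members and lower for 6 (120 and 6 adjusted over the list alone, and 126 and 2 as deposited), and the list's median lay 0.43 log2 above matched lists, at percentile 100. PABPC1, the poly(A)-binding protein, was higher by 1.04 ± 0.02 and EEF1A1 by 0.58 ± 0.02, while EIF4G2, a translation initiation factor, stood at -0.17 ± 0.02 and at 0.55 as deposited. ER-targeted mRNAs were higher for 51 of 66 and lower for 10 (51 and 10 adjusted over the list alone, and 63 and 0 as deposited), with a median 0.01 above matched lists (percentile 53.7) that became -0.03 without either NES replicate. CANX was higher by 1.07 ± 0.02 and TFRC, the transferrin receptor, by 0.30 ± 0.02, though with the median of site rates TFRC stood at 0.058 and did not pass (adjusted p = 0.19). TFRC also belongs to the erythroid list, of which 13 of 17 members were higher and 1 lower (13 and 1 adjusted over the list alone, 16 and 1 as deposited, percentile 89.2). The globins HBG2 and HBE1 were higher by 1.02 ± 0.06 and 0.86 ± 0.04, and SLC25A37, a mitochondrial iron importer, was lower at -1.85 ± 0.06. With the median of site rates HBE1 stood at 0.21 and did not pass (adjusted p = 0.054). Nuclear-encoded mitochondrial mRNAs were higher for 25 of 28 and lower for 1 (25 and 1 adjusted over the list alone, 28 and 0 as deposited, percentile 94.5), with CYCS at 1.23 ± 0.04.

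Nuclear-retained RNAs were, relative to the median gene, lower with NES in K562 for 4 of 6 members and higher for 1 (4 and 1 adjusted over the list alone), but as deposited 1 was lower and 4 higher. Their median lay -0.62 log2 from matched lists, at percentile 0.980, which became 7.09 without NES replicate 1, 12.7 without NES replicate 2, 3.75 at a minimum of 10 sites and 4.07 with no filter on sites, so that the list no longer stood apart. By number of called sites, 7 nuclear-retained members lay -0.89 log2 from matched lists (percentile 1.4). PVT1, a long noncoding RNA of the MYC locus, was the member with a higher rate (0.78 ± 0.09), and TUG1 stood at -0.50 ± 0.04 relative to the median gene and 0.22 as deposited. On the same relative scale, histone mRNAs were lower for 8 of 10 members and higher for 2 (8 and 2 adjusted over the list alone, but 1 lower and 3 higher as deposited, percentile 0.0400), with the linker histone H1-2 higher by 1.41 ± 0.06 and H2BC21 at -0.90 ± 0.06. Cytoplasmic long noncoding RNAs were higher for 7 of 10 and lower for 3 (7 and 3 adjusted over the list alone, 8 and 1 as deposited, percentile 85.0): ZFAS1 was higher by 0.98 ± 0.05, SNHG1 lower at -0.99 ± 0.04, and NORAD stood at -0.72 ± 0.02 relative to the median gene and at 0.000224 as deposited. ADAR-site mRNAs were higher for 4 of 16 and lower for 8 (4 and 8 adjusted over the list alone, but 14 higher and 1 lower as deposited, percentile 10.8), with CCNI at 0.95 ± 0.03.

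The NES against NLS changes of the cell lines, which share no library, ran together across genes. Over 5534 genes tested in both, Pearson's r was 0.826 and Spearman's rho 0.824, across genes that are not independent replicates. Relative to each line's median, 1594 genes were higher with NES in both lines, against 792 if the lists were independent, and 1429 were lower in both, against 632. Opposite calls numbered 65 in each direction.

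**Figure D2:**
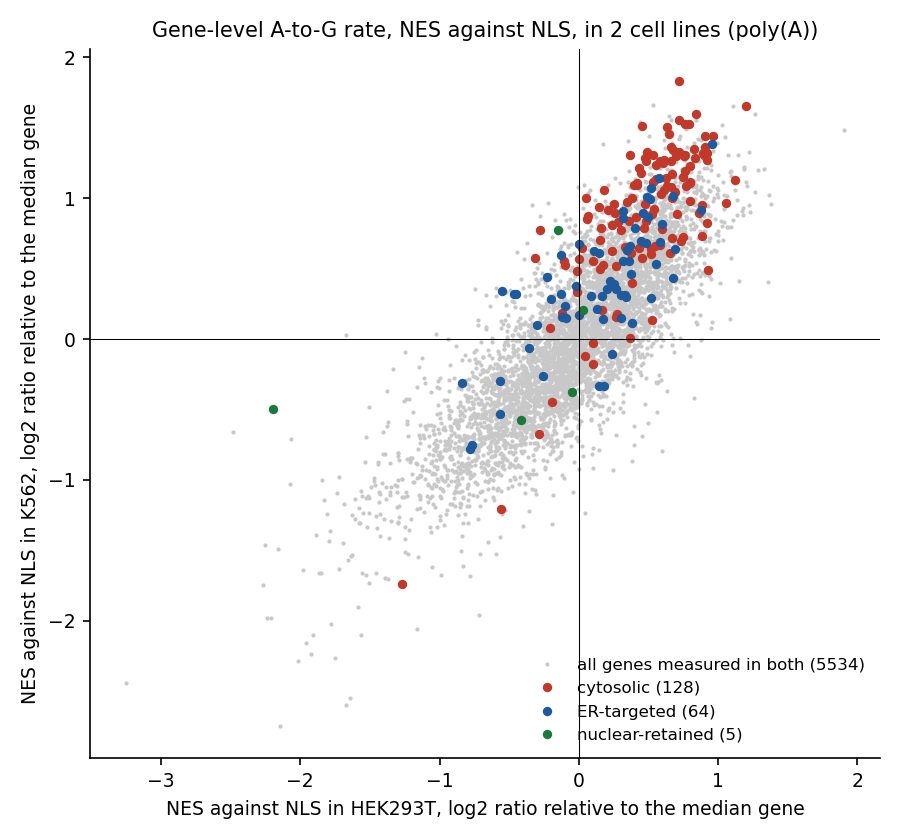
Log2 change with NES against NLS relative to the median gene in K562 (vertical axis) against HEK293T (horizontal axis); each point is 1 of 5534 genes, with the cytosolic, ER-targeted and nuclear-retained lists in colour. The points lie along the diagonal (r = 0.826), and the 128 cytosolic mRNAs sit mostly above 0 on both axes.

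rRNA-depleted libraries brought RNAs without a poly(A) tail into the comparison of NES with NLS in HEK293T. Lowest with NES was RMRP, the RNA of RNase MRP, with 0.365% ± 0.0810 against 19.7% ± 0.428 over 9 shared sites. MALAT1 had 0.713% ± 0.0670 against 18.3% ± 0.278 over 159, the telomerase RNA TERC 1.92% ± 0.00372 against 40.9% ± 0.730 over 7, the RNase P RNA RPPH1 1.89% ± 0.366 against 17.5% ± 0.227 over 14, and RN7SK, which holds the elongation factor P-TEFb inactive, 1.80% ± 0.267 against 16.2% ± 0.156 over 43. The ribosomal RNA precursor RNA45SN1 had 2.274% ± 0.390 against 20.9% ± 0.582 over 30. Among the genes highest with NES were histone mRNAs, which end without a poly(A) tail: H1-2 had 7.39% ± 2.69 against 1.65% ± 0.199 and H3C2 6.41% ± 2.82 against 2.04% ± 0.0937. The median of the 5356 genes was 0.03 above 0. Called genes numbered 66 higher and 187 lower as deposited, and 51 and 195 relative to the median. With each library centred on its own median gene they numbered 726 and 783, so the counts and their balance depend on the scaling. At an unadjusted p under 0.05 limma gave 882 and 876 genes in total on the 2 scales.

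On the scale relative to the median gene, RMRP stood at -5.80 ± 0.25, MALAT1 at -4.71 ± 0.23, TERC at -4.44 ± 0.26, RPPH1 at -3.25 ± 0.23, RNA45SN1 at -3.24 ± 0.23 and RN7SK at -3.21 ± 0.23, with adjusted p-values of 1.1e-39 or less that rest on a spread pooled over genes. H1-2 was higher by 2.10 ± 0.23 (adjusted p = 1.5e-16), LINC00632 by 1.56 ± 0.24, H3C2 by 1.55 ± 0.23, H3C10 by 1.35 ± 0.23, H2AC20 by 1.34 ± 0.23 and CKS1B by 1.28 ± 0.23. These counts depended on single libraries: as deposited, 1853 genes were higher and 443 lower without NES replicate 1, 331 and 1496 without NES replicate 2, 1 and 9 without NLS replicate 1, and 2 and 9 without NLS replicate 2. With 1 NES library left the spread came from the NLS pair alone, and with 1 NLS library left from the NES pair alone, so calls gained or lost in these fits are not by themselves evidence for or against a difference. RMRP, MALAT1, TERC, RPPH1, RNA45SN1, RN7SK and H1-2 passed with any 1 of the 4 libraries left out. LINC00632 did not pass without NLS replicate 1 (adjusted p = 0.22), and H3C2 passed neither without it (adjusted p = 0.41) nor without NLS replicate 2 (adjusted p = 0.26). H3C10, H2AC20 and CKS1B likewise did not pass without either NLS replicate (adjusted p = 0.073 to 1.00).

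In rRNA-depleted RNA, nuclear-retained RNAs were lower with NES for 6 of 7 members and higher for 0 (6 and 0 adjusted over the list alone), with a median -3.24 log2 from matched lists, at percentile 0. TUG1 stood at -1.10 ± 0.24, though it did not pass without NLS replicate 1 or NLS replicate 2 (adjusted p = 1.00 and 0.82), and PVT1 was not called (0.44 ± 0.23, adjusted p = 0.33). Without NES replicate 1 or NES replicate 2 it stood at 0.34 and 0.54 and passed, but on the spread of the NLS pair alone. Called sites differed in number too: MALAT1 had 161 with NES and 1350 with NLS, NEAT1 3 and 845, KCNQ1OT1, an antisense long noncoding RNA, 0 and 149, and SCARNA2, a small RNA of Cajal bodies, 4 and 44. By number of called sites, 13 members of the list lay -2.94 log2 from matched lists (percentile 0). Histone mRNAs were higher for 9 of 17 members and lower for 2 (12 and 2 adjusted over the list alone, percentile 100), with H4C3 at 1.20 ± 0.23 and H1-4 at 0.96 ± 0.23. Both of these lost their call without NLS replicate 1 (adjusted p = 0.50 and 1.00) or NLS replicate 2 (1.00 for each). Histone members share close sequences, and how the authors placed reads among them is not given in the sources used here.

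Other lists stood nearer to the median gene in rRNA-depleted RNA. Cytosolic mRNAs were lower for 8 of 127 and higher for 0 (10 and 1 adjusted over the list alone, percentile 88.1), with EEF1A1 at -0.97 ± 0.23 (no call without NLS replicate 1 or NLS replicate 2, adjusted p = 1.00 for each) and HSP90AA1 not called at 0.07 ± 0.23 (-0.07 without NES replicate 1 and 0.22 without NES replicate 2, opposite in direction, with calls that rest on the spread of the NLS pair alone). The list's median moved from 0.04 above matched lists to -0.03 without NES replicate 2. ER-targeted mRNAs were lower for 2 of 66 and higher for 0 (2 and 0 adjusted over the list alone, percentile 50.05), and CANX was not called at 0.57 ± 0.23 (adjusted p = 0.17). Without NES replicate 1 or NES replicate 2 it stood at 0.60 and 0.53 and passed, on the spread of the NLS pair alone. Without 1 replicate the ER list's median lay between -0.06 and -0.01 from matched lists. Cytoplasmic long noncoding RNAs were higher for 1 of 8 and lower for 1 (1 and 1 adjusted over the list alone), at percentile 97.41, within the middle 95%. It lay outside without NES replicate 2 (99.5), among lists matched on rate alone (97.88), with the mean of log2 site rates (98.8) and on the log2 odds (97.75). Its member SNHG1 stood at -1.0 ± 0.23 (no call without NLS replicate 1 or NLS replicate 2, adjusted p = 1.00 for each). Nuclear-encoded mitochondrial mRNAs were lower for 1 of 27 and higher for 0 (1 and 0 adjusted over the list alone, percentile 72.6). ADAR-site mRNAs were lower for 1 of 14 and higher for 0 (1 and 0 adjusted over the list alone, percentile 69.8). That gene was FLNA, filamin A, at -1.19 ± 0.23, again without a call when NLS replicate 1 or NLS replicate 2 was left out (adjusted p = 1.00 for each). The 4 erythroid members gave 0 calls (0 adjusted over the list alone, percentile 76.6). Across 4987 genes, the changes in poly(A) and rRNA-depleted RNA, which share no library, had a Pearson's r of 0.617 and a Spearman's rho of 0.571. Relative to the median, 38 genes were higher in both (15.5 if independent), 136 lower in both (51.8) and 4 opposite, 3 of them higher in poly(A) RNA.

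**Figure D3:**
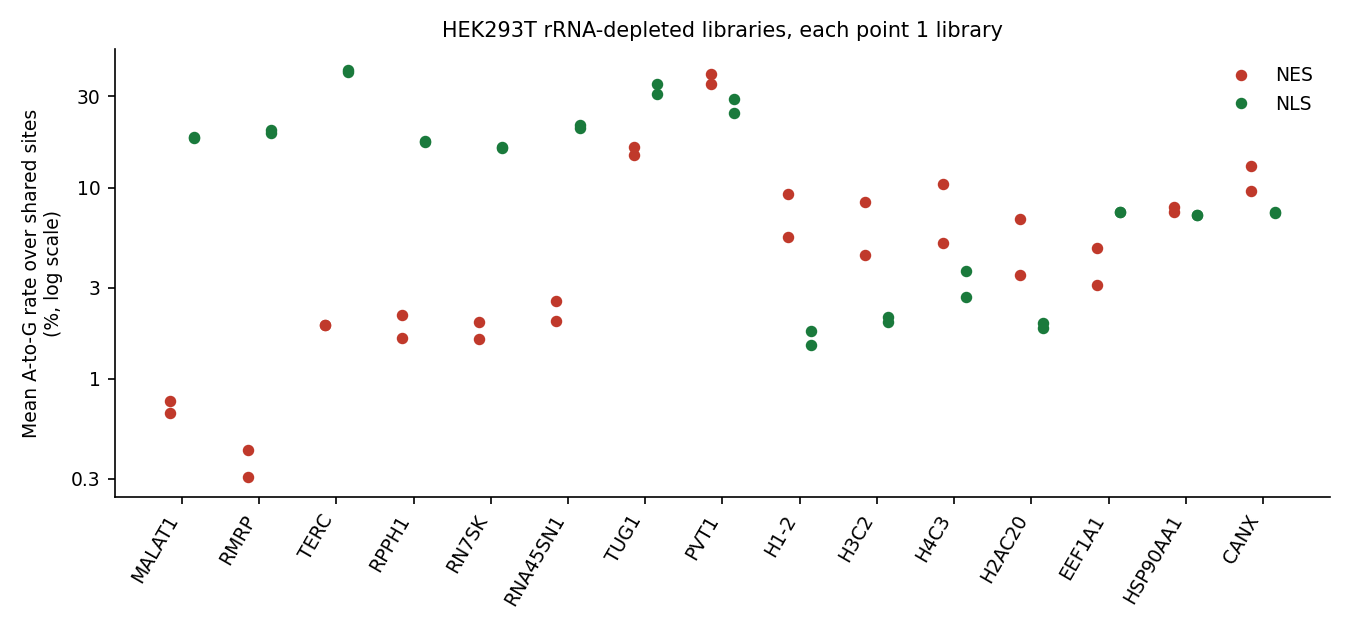
A-to-G rate in percent (vertical log axis) over shared sites of nuclear RNAs and histone mRNAs in rRNA-depleted HEK293T RNA with NES and with NLS; each point is a library. RMRP, MALAT1, TERC, RPPH1, RNA45SN1 and RN7SK lie lower with NES, and H1-2 and H3C2 lie higher.

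The classes of the sites also differed by construct. Long noncoding RNAs held 0.407% of NES sites (95% interval 0.394% to 0.420%) and 1.03% of NLS sites (1.01% to 1.06%) in HEK293T poly(A) RNA, 0.529% and 2.29% in rRNA-depleted RNA and 0.747% and 1.34% in K562, with 0.449% for ERM. RNAs of the nuclear-retained list held 277 NES and 912 NLS sites in HEK293T poly(A) RNA, 315 and 2746 in rRNA-depleted RNA and 676 and 1435 in K562. Sites more than 500 bases from every K562 NES poly(A) site of the same gene were 2.22% of NES, 2.63% of NLS and 0.981% of ERM sites in poly(A) RNA, and 3.64% of NES and 6.85% of NLS sites in rRNA-depleted RNA. Among poly(A) sites with a rate of 10% or more the shares were 3.80% of NES, 6.30% of NLS and 1.92% of ERM sites. The reference sites were made with NES, which by construction can place NES sites nearer to them than NLS sites, so these shares do not by themselves measure a difference between the constructs. Whether such sites lie in introns or untranslated regions was not analysed here. Mitochondrially encoded RNAs had no gene with 5 shared sites and were not compared by rate. They held 58 sites with NES at a mean of 0.359%, 15 with NLS at 0.430% and 85 with ERM at 0.944% in HEK293T poly(A) RNA. In K562 they held 4 with NES at 3.22% and 43 with NLS at 0.126%. These means are over different sites.

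Site sets overlapped most between ERM and NES. Of the smaller table's sites, 95.9% were shared between ERM and NES, 77.1% between NLS and NES and 74.3% between ERM and NLS in HEK293T poly(A) RNA. The shares were 75.6% for NES and NLS in K562 and 59.1% in rRNA-depleted RNA. Between the cell lines, 69.5% were shared for NES and 64.7% for NLS, and between poly(A) and rRNA-depleted RNA 83.0% for NES and 63.0% for NLS. Rates over shared sites had a Pearson's r across sites, which are not replicates, of 0.902 between HEK293T and K562 for NES and 0.893 for NLS, against 0.667 between NES and NLS within HEK293T poly(A) RNA and 0.882 between ERM and NES. A shared share depends on how many sites each table lists.

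Total RNA libraries showed the same enzymes on ribosomal and spliceosomal RNA. All 5 small nuclear RNA positions called with both constructs were lower with NES. U1 position 103 had 5.01% ± 0.353 with NES and 65.3% ± 1.48 with NLS, U1 position 104 had 3.86% ± 0.0393 and 62.8% ± 0.822, U2 position 88 had 3.46% ± 0.189 and 67.6% ± 0.0146, and U2 position 75 had 1.91% ± 1.11 and 54.5% ± 0.128. The mean difference over the 5 positions was -49.9 points, with an exact sign permutation p of 0.0625 across positions, the smallest that 5 positions allow. U4 had 11 called sites and U5 had 1, with NLS alone, and U4 position 100 reached 58.8% ± 0.208. Position 771 of 18S rRNA, a part of the small ribosomal subunit, had 46.0% ± 0.0383 with NES and 20.4% ± 0.0763 with NLS. Over 14 shared rRNA positions, 8 were higher and 6 lower with NES, with a mean difference of 2.26 points (exact sign permutation p = 0.291), and at 11 of them the replicates of the constructs did not overlap. Of these positions, 9 in 28S rRNA rest on an offset of 7924 bases between the numberings of the tables, inferred from the positions themselves, and 5.8S rRNA was left out because its offset was ambiguous.

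In tRNA, where each construct had 1 library beside 1 control library, valine and isoleucine tRNAs carried the highest rates above control. Position 35 of tRNA ValTAC, the middle base of its anticodon, was changed in 52.6% of 190 reads with NES (95% exact interval 45.3% to 59.9%), 26.4% of 277 with NLS and 27.4% of 321 with ERM, against 0 of 117 control reads, which allows up to 3.10%. Position 35 of ValCAC had 41.6%, 19.6% and 18.01% against 0 of 166, position 36 of IleAAT had 32.9%, 20.2% and 15.7% against 0 of 138, and position 35 of ValAAC had 14.9%, 5.77% and 3.78% against 0 of 315. Of 13 tested adenosines at the middle of an anticodon, 8 were called higher than control with each construct, as was 1 of 5 at its last base, in the selenocysteine tRNA. Outside the anticodon the calls were 9 of 970 with NES, 9 with NLS and 5 with ERM, of which 6, 4 and 3 lay at the last base of the tRNA (AspGTC, GluCTC, GluTTC). Position 75 of AspGTC had 11.8% with NES, 2.10% with NLS and 4.85% with ERM against 0.141%, and position 75 of GluTTC had 6.58%, 6.05% and 7.69% against 3.47%. Position 12 of GlyTCC had 0.870%, 9.88% and 0.304% against 0 of 148, and position 36 of GlyCCC had 7.22%, 3.78% and 1.68% against 0 of 181. Positions near 100% in every library, control included, were LeuTAG 43, IleAAT 35 and ValAAC 34 (93.5% to 99.2% in the control); the last of these is the first anticodon base of ValAAC, a textbook site of inosine, as IleAAT 35 is in its tRNA. Fisher's exact test (two-sided, Benjamini-Hochberg adjusted) called 18 of 1079 positions higher with NES, 18 of 1110 with NLS and 14 of 1111 with ERM, and 0 lower, where 28, 32 and 22 positions passed at an unadjusted p under 0.05. The authors' deposited table gave 17, 17 and 14 positions at an adjusted p under 0.05. Such a test compares these libraries and not the constructs, and pooled reads ranged from 958289 in the control to 2618369 with ERM, of which 53.5% to 56.1% fell on 1 cluster of GluCTC.

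Structure and neighbours of the changed tRNA adenosines were compared with those of the other tested adenosines. Positions at the last base of the tRNA were left out of this comparison, 52 tested and 6 of them called with NES. Of the 12 remaining called positions with NES, 58.3% had an unpaired probability above 0.5, against 57.1% of 1015 others (Fisher's exact p = 1). The base after was C at 75.0% of called and 20.4% of other positions with NES, 64.3% and 20.4% with NLS and 81.8% and 20.5% with ERM, and G came before 0 called positions. These shares were not tested, and several called positions are the second anticodon base of related valine tRNAs. The base before was T at 33.3% of called and 24.3% of other positions with NES, and Fisher's exact p for T was 0.501 with NES, 0.0530 with NLS and 0.480 with ERM.

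Genomic DNA of K562 was compared between NLS and control, 1 library each, to ask whether the nuclear enzyme changed DNA. Over 878631 listed sites the pooled rate was 21.8% with NLS and 22.2% in the control, and over the 102614 sites with at least 20 reads in both it was 5.48% and 5.63%. At the 60642 of these with a control rate under 30%, a choice made on the control that favours NLS, it was 1.432% with NLS (95% interval 1.427% to 1.436%) and 1.372% in the control (1.368% to 1.376%), with 2168 sites higher and 1069 lower at an unadjusted p under 0.05, and 3 and 0 after adjustment. Of the 102614 sites, Fisher's exact test called 5 higher and 6 lower with NLS. At 50 reads or more it called 0 in either direction, with a smallest adjusted p of 0.0629 and 939 higher and 1029 lower at an unadjusted p under 0.05. The authors' deposited table gave 3374 sites at an unadjusted p under 0.05 and 0 after adjustment. The 6 sites with the highest rates and at least 100 reads stood at 100% with NLS and 99.7% to 100% in the control. Of the K562 NLS poly(A) sites, 33 were among the listed DNA sites, or 0.00589%. At these 33 the pooled rate was 1.78% with NLS and 0.227% in the control, and at the 19 of them with at least 20 reads in both it was 0.157% and 0.137%. The other sites had fewer than 20 reads in at least 1 of the libraries.

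Single HEK293T cells with NES showed how far 1 cell follows the bulk. The 10 cells carried 146445 to 551317 sites (median 334553), with a mean rate per cell of 20.9% to 39.3% (median 31.6%) and between 47.4% and 56.9% of their sites in the bulk NES poly(A) table. The median over cells of the mean rate was 29.3% at bulk NES sites and 34.0% elsewhere. A median of 10.2% of a cell's sites stood at 100%. Across shared sites, each cell's rates had a Pearson's r of 0.264 to 0.491 with the bulk rates, and the 45 pairs of cells had 0.384 to 0.729. The 17669 sites measured in all 10 cells had a mean rate per cell of 9.34% to 22.1%. The mean of the cells at 16080 of them had an r of 0.884 with bulk NES, and at the 15484 also called with NLS an r of 0.886 with NES and 0.689 with NLS. At the 16080 sites the mean rate was 16.4% in the cells and 18.2% in bulk NES, so the cells were not higher at these sites. They are a small part of the 83269 to 278395 sites that each cell shared with bulk NES. The bulk rate at each cell's own shared sites was not computed, so the comparison does not extend to them. In single cells the 2 bulks were barely apart: over sites called with both, a cell's r was 0.270 to 0.532 with NES (median 0.409) and 0.305 to 0.458 with NLS (median 0.395). It was higher with NLS in 4 of the 10 cells, cell 1 (0.270 with NES, 0.305 with NLS), cell 3 (0.3540, 0.3548), cell 7 (0.402, 0.410) and cell 10 (0.393, 0.412). Values are given per cell, and constructs were not compared in single cells.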

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

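For nuclear-retained and cytosolic RNAs the tests below were chosen only after the result was seen, while the 3 tests on cell division were written down before they were run.

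The NES against NLS change was set side by side in K562 and HEK293T over 284332 sites called in all 4 tables. What drew attention here was the difference between the cell lines, tested by limma for 5135 genes. Relative to the median of each line, 1087 genes changed more towards NES in K562 and 699 more towards NLS, against 1495 and 448 as deposited. The genes furthest towards NES in K562 were the long noncoding RNA TUG1 (difference 2.11, from log2 -2.33 in HEK293T to -0.21 in K562) and the proliferation marker MKI67 (2.01, from -1.89 to 0.12). They were followed by the spindle protein ASPM (1.97, from -2.20 to -0.23), TSPYL2 (1.84, from -2.59 to -0.75), FAM72B (1.59, from -1.38 to 0.22) and cyclin B1, CCNB1 (1.29, from -1.41 to -0.12). Furthest towards NLS in K562 were the actin regulators TWF1 (-1.54, from 0.59 to -0.95) and WASL (-1.33, from -0.07 to -1.40), RPL22L1 (-1.39, from -0.37 to -1.76), SH2B1 (-1.20, from 0.21 to -0.99), the vesicle protein VAMP3 (-1.19, from 0.14 to -1.06) and CHCHD7 (-1.16, from 0.49 to -0.67).

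MKI67, ASPM, CCNB1 and CENPF, seen among the genes furthest apart, led to a list of G2/M mRNAs from which these 4 were removed. G2/M mRNAs as a set lay at percentile 100 of lists matched on number of sites and rate (55 members, 33 higher and 1 lower in K562, median -0.35 in HEK293T and 0.11 in K562). S phase mRNAs as a set lay at percentile 5.005 (39 members, 4 higher and 10 lower). A high place was not particular to G2/M mRNAs. Under the same matching the cytosolic (percentile 100), histone (99.9), ER-targeted (99.5), erythroid (99.3) and cytoplasmic long noncoding (99.3) lists also stood apart. Nuclear-retained, nuclear-encoded mitochondrial and ADAR-site lists did not. The scale of the change in HEK293T left the G2/M list at percentile 100 among lists matched on it. A difference between the lines in where G2/M mRNAs reside may underlie the place of the G2/M list, as may a difference in cell cycle stage among sorted cells, and the data do not separate the 2. Nor do they exclude a cause shared with the other lists that stood apart.

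Nuclear-retained RNAs were lower with NES than with NLS in rRNA-depleted RNA. For read depth over these RNAs, the list lay at percentile 0 of lists matched on the depth proxy and rate, so genes alike in both did not fall as far. The proxy was not checked against read depth, which is unknown, so the test cannot exclude depth as the cause. Cytoplasmic long noncoding RNAs did not fall as a list, at percentile 97.41 (8 members, 1 called higher and 1 lower). RMRP, TERC, RPPH1 and RN7SK, all lower with NES, are outside that list. The test therefore does not decide for noncoding RNAs as a class. A single replicate of the rRNA-depleted NES libraries did not account for the lower nuclear-retained list, since the highest percentile without either was 0.

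Cytosolic mRNAs were lower with ERM than with NES. A high NES rate by itself is unlikely as the cause, since the list lay at percentile 0 of lists matched on that rate alone. Saturation at high NES rates would narrow the gap to ERM and not widen it. Setting it aside therefore lends no support to an effect of place. For mRNAs at the ER edited more with ERM, ER-targeted mRNAs lay 0.0795 log2 above cytosolic mRNAs (permutation p = 0.0150, 70 and 129 genes). The medians against their bins were -0.03 and -0.11, so the difference came from the cytosolic list lying lower and not from the ER-targeted list lying above 0.

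Single cell 1 lay far from the other 9 in its median site rate, 1.50376%, by Dixon's test (gap over range 0.485, critical value 0.466). Of 7 measures tested 1 passed. About 1 in 20 groups passes by chance for a single measure, and with 7 measures the chance of at least 1 pass is higher.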

How the results depend on the processing

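Of 1580 alternative values for named genes, 1519 kept direction and side of the threshold, 43 lost the call, 5 gained one and 13 turned direction. For lists, 455 of 514 kept their place, 12 lost it, 9 gained it and 38 turned direction, most of them ER-targeted medians near 0. Centring moves all genes of a comparison alike, so the alternatives on centring could not change a list's place. They are counted among those that kept it and say nothing on robustness. Counts of genes kept within 1.5 times in 134 of 164 alternatives. For every changed result below the cause was not tested, apart from changes of scale that follow from centring. Alternatives on the summary of sites per gene, trend, odds, centring of libraries, rate matching and sites of all 3 constructs were chosen after seeing the data. Minimum coverage on fraction tables, control rates, pooled reads, another count model, 3' UTR and coding sequence, sequence context of mRNA and coverage in single cells were not run, since depth and a genome are not given in the sources used here. Depth is unknown for every fraction table, so a site absent from a table is not a site without change.

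As deposited, CALU stood at 0.46 and EEF1A1 at 0.34 for NES against NLS in HEK293T poly(A) RNA; CANX at -0.60, DANCR at -0.23 and JPX at -0.32 for ERM against NES; and EIF4G2 at 0.55, NORAD at 0.000224 and TUG1 at 0.22 in K562. The cell line difference had 448 genes lower. Relative to the median, genes higher and lower numbered 2218 and 2150 for NES against NLS in HEK293T, 886 and 1442 for ERM against NES and 2437 and 2432 in K562. With each library centred they numbered 2474 and 2069, 867 and 1620, 2640 and 2254, and 726 and 783 in rRNA-depleted RNA.

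With the replicate number as a block, that is with libraries paired by number, genes higher and lower were 5217 and 400 for NES against NLS in HEK293T, 4 and 6321 for ERM against NES, 2375 and 1309 for ERM against NLS, 5238 and 387 in K562 and 60 and 171 in rRNA-depleted RNA. CANX did not pass for ERM against NES with the block (adjusted p = 0.061). Deviations of replicates with the same number had correlations of 0.000879, -0.0209, 0.00432, -0.00663 and 0.0894 across genes. Little deviation was shared by number, which cannot show whether libraries of the same number were made together.

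At a minimum of 10 shared sites, r between cell lines was 0.837 and between poly(A) and rRNA-depleted RNA 0.636. ER-targeted medians were -0.0108 for ERM against NLS, -0.0112 in K562 and -0.00597 in rRNA-depleted RNA, nuclear-retained RNAs in K562 stood at -0.56 (percentile 3.75, no longer apart), and 1 gene was higher with ERM than NES. With no filter on sites, r was 0.770 and 0.534, and 18 genes were higher with ERM than NES. For ERM against NLS, ER-targeted mRNAs then stood at -0.053, cytoplasmic long noncoding RNAs at 0.24 (percentile 92.0, no longer apart), ADAR-site mRNAs at 0.020 and nuclear-retained RNAs at -1.66 (percentile 0.015, standing apart). Nuclear-encoded mitochondrial mRNAs stood at -0.00357 for ERM against NES, nuclear-retained RNAs at -0.50 in K562 (percentile 4.07, no longer apart) and erythroid mRNAs at -0.13 in rRNA-depleted RNA.

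Under the mean of log2 site rates, CANX stood at -0.047 for ERM against NES and EEF1A1 at 0.19 for NES against NLS. ER-targeted mRNAs stood at -0.043 for ERM against NLS, -0.029 for NES against NLS and -0.00373 in rRNA-depleted RNA. Cytoplasmic long noncoding RNAs stood at 0.010 for ERM against NES and 0.29 in rRNA-depleted RNA (percentile 98.8, standing apart), cytosolic mRNAs at -0.039 for ERM against NLS and nuclear-encoded mitochondrial mRNAs at 0.13 for NES against NLS (percentile 90.8, no longer apart). Under the median of site rates, CANX stood at -0.085 and EEF1A1 at 0.33 in the same comparisons. ER-targeted mRNAs stood at -0.00538 for ERM against NLS, -0.021 for NES against NLS and -0.057 in rRNA-depleted RNA. Nuclear-encoded mitochondrial mRNAs stood at 0.11 for NES against NLS (percentile 86.3, no longer apart), -0.0202 in K562 and -0.0161 in rRNA-depleted RNA, and 1220 genes were higher with ERM than NLS. On the log2 odds, ER-targeted mRNAs in K562 stood at -0.020 and cytoplasmic long noncoding RNAs in rRNA-depleted RNA at 0.30 (percentile 97.75, standing apart).

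Among lists matched on rate alone, ER-targeted mRNAs stood at -0.0115 and cytoplasmic long noncoding RNAs at 0.27 (percentile 95.6, no longer apart) for ERM against NLS, the latter at 0.25 in rRNA-depleted RNA (percentile 97.88, standing apart), histone mRNAs at 0.057 for NES against NLS and nuclear-encoded mitochondrial mRNAs at -0.019 for ERM against NES. Over sites of all 3 constructs, ER-targeted mRNAs stood at 0.00524 and erythroid mRNAs at 0.41 (percentile 99.4, standing apart) for ERM against NES, with 2 genes higher. ER-targeted mRNAs then stood at -0.00951 and nuclear-encoded mitochondrial mRNAs at 0.14 (percentile 95.3, no longer apart) for NES against NLS, with 173 genes lower.

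At a site rate of 5% or more, the long noncoding share differed between NLS and NES by 0.595 points in HEK293T, 1.31 in rRNA-depleted RNA and 0.638 in K562, and at 10% or more by 0.800, 1.05 and 0.846. The share of sites over 500 bases from K562 NES sites, a reference made with NES, differed by 0.904 and 3.60 points at 5% and by 2.5 and 4.40 at 10%, in poly(A) and rRNA-depleted RNA. Shared shares at 5% and 10% were 94.9% and 92.1% for ERM and NES, 61.2% and 43.1% for ERM and NLS, 70.3% and 57.1% for NES and NLS in HEK293T, 69.7% and 58.2% in K562 and 56.5% and 52.8% in rRNA-depleted RNA. They were 70.8% and 70.6% between cell lines for NES and 61.7% and 57.2% for NLS, and between poly(A) and rRNA-depleted RNA 73.9% and 61.8% for NES and 45.2% and 38.9% for NLS. In tRNA with ERM, 9 positions passed at 100 reads and 9 lay 5 points above control. In genomic DNA, sites with a control rate under 30% gave 3 higher and 0 lower, and 50 reads or more gave 0 and 0. The median over cells of the mean rate was 15.7% at sites in all 10 cells.

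With 1 library left out in turn, lists gave these lowest and highest medians against matched lists. For NES against NLS in HEK293T: ER-targeted -0.056 and 0.079, histone -0.24 and 0.21, nuclear-encoded mitochondrial 0.15 and 0.22, erythroid 0.30 and 0.49. For ERM against NES: cytoplasmic long noncoding -0.036 and 0.060, nuclear-encoded mitochondrial -0.057 and 0.040, nuclear-retained 0.037 and 0.31, with 1 to 8 genes higher. For ERM against NLS: cytoplasmic long noncoding 0.21 and 0.34, ER-targeted -0.045 and 0.025, cytosolic 0.00503 and 0.089. In K562: ER-targeted -0.034 and 0.063, nuclear-retained -0.66 and -0.36. In rRNA-depleted RNA: cytoplasmic long noncoding 0.12 and 0.35, cytosolic -0.027 and 0.036, ER-targeted -0.0574 and -0.00523, the gene HSP90AA1 -0.069 and 0.22, with 1 to 1853 genes higher and 9 to 1496 lower, and the overall rate difference -1.33 and 2.43 points. With 1 library of a construct left, the spread in rRNA-depleted RNA came from the other construct's pair alone.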

Other observations

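Fixed lists were also placed in the difference between the cell lines, and these tests were chosen only after the result was seen. Cytosolic mRNAs changed more towards NES in K562 for 94 of 128 members and less for 11, with a median 0.20 log2 above matched lists (percentile 100). ER-targeted mRNAs followed with 33 of 64 and 5 (percentile 99.5), cytoplasmic long noncoding RNAs with 5 of 9 and 1 (percentile 99.3) and erythroid mRNAs with 2 of 4 and 0 (percentile 99.3). Histone mRNAs had 3 of 3 and 0 (percentile 99.9). Nuclear-retained RNAs (percentile 38.5), nuclear-encoded mitochondrial mRNAs (percentile 34.1) and ADAR-site mRNAs (percentile 19.7) stood within the middle 95%.

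Called sites of named RNAs differed in number between the tables. TUG1 had 88 sites with NES, 523 with NLS and 20 with ERM in HEK293T poly(A) RNA, and 257 with NES and 239 with NLS in K562. MALAT1 had 32 with NES and 971 with NLS in K562. In rRNA-depleted RNA, RMRP had 9 and 37, TERC 7 and 40, RPPH1 14 and 41, RN7SK 43 and 56 and RNA45SN1 32 and 283. Histone mRNAs held 557 NES and 366 NLS sites in rRNA-depleted RNA and 682 and 491 in K562 poly(A) RNA. Numbers of sites move with the abundance of an RNA and with depth, which are not given in these tables.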
